A study of Brassica napus with 6 samples.

How the data were processed

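Poly(A) RNA of Brassica napus, an allotetraploid oilseed crop that carries an A and a C subgenome, was sequenced in 6 libraries. Per the labels, 3 libraries came from WT plants and 3 from mutant plants, all grown in an experimental field. The plants were F2 individuals of opposite extreme phenotypes, chosen in a search for genes linked to the double flower. Each sample held the shoot tip together with buds under 1 mm. The tissue label reads flower bud, whereas the extraction protocol names cotyledon with 3 replications. This conflict was not resolved, and the samples are described here as flower bud. The labels do not say whether a library held 1 plant or several, so p-values measure only the spread between these samples, which may be technical.

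The authors deposited a table with raw read counts and FPKM values per gene for each library, per the file headers, beside gene positions, coding lengths, best Swiss-Prot matches, Gene Ontology terms and KEGG orthologs. The aligner, the counting tool and the genome build are not given in the sources used here. Coordinates are those of the deposited table, counted from 1. Every listed gene length was a multiple of 3, so lengths are coding lengths. The deposited FPKM values gave back the column totals of the counts from count, length and FPKM in all genes, within a relative tolerance of 1e-06. The table held 101038 genes, and 67.6% of them carried a Swiss-Prot match. None of its identifiers matched the RefSeq gene table (0 matches), so names come from the deposited Swiss-Prot column. A name such as AP2 therefore means that the best protein match of the gene was Arabidopsis AP2, and a family member can carry the name of a relative. Closely similar A and C copies can share reads, and how the counting split them is not given in the sources used here, so values of single copies are uncertain.

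Counts were analysed in R 4.3.3 with edgeR 4.0.16 as the main test. Genes passed the filterByExpr rule by group, TMM factors scaled the libraries, and a quasi-likelihood F test (legacy setting) compared mutant with WT, 3 against 3, with no covariate. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Expression is given in CPM after TMM scaling as mean ± SD over 3 libraries, and log2 fold changes are mutant over WT. Standard errors are the absolute log2 fold change divided by the square root of F. DESeq2 1.42.0 and limma 3.58.1 (voom, and limma on log2 FPKM plus 1 or 0.1) were alternatives. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1 prepared the tables and ran the position analysis. Total counts ran from 13876719 to 15140165 per library, and 3 counts, the limit that a count of 0 allows, corresponded to between 0.198 and 0.216 CPM. No pair of libraries agreed within sampling noise (chi-square over degrees of freedom at least 12.5), so all 6 were kept.

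The tests, the alternatives, 22 gene lists and the rule for named genes were fixed before the data were examined. The lists cover floral organ identity, regulators of AGAMOUS and floral boundaries, shoot and floral meristem, flowering time, anther and pollen wall, mature pollen, carpel and ovule, starch and sucrose, pectin, ethylene, auxin, cytokinin, gibberellin, jasmonate, photosynthesis, vascular tissue, epidermis, root, cell division, abiotic stress, wounding and defence, and petal growth and pigment. Of 260 listed symbols, 238 matched at least 1 gene, and 16 of them matched over 12 genes. Lists with at least 5 tested genes were tested with limma camera (correlation 0.01, and estimated) and fry on log2 CPM. The naming rule took the 10 higher and 10 lower genes with the largest fold change among those past the threshold, which gave none, then up to 4 members called within each list, or the 2 with the highest mean, and every tested copy of AG, AP1, AP2, AP3, PI, SEP3, WUS, CLV3 and ERS2. The genes with the smallest adjusted p were named after their values were seen. Copies of AG and AP1 whose best match was a Brassica entry were added after the data were seen. Sums of CPM over all tested copies of a symbol were compared by a two-sided exact permutation test, which cannot go below 0.1 with 3 against 3.

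Terms with at least 10 tested members and the 19 chromosomes were tested by Fisher's exact test, against genes that carry a term of that kind and against all tested genes. The deposited terms are identifiers without names, and the names printed are background knowledge of those identifiers. Because the main test called no gene, terms and chromosomes were described from the DESeq2 calls, a choice made after seeing the data. For the position analysis, also chosen then, genes with a mean of at least 2 CPM were centred as log2(CPM + 0.5) per gene and per library and summarised by their median in windows of 2 Mb with at least 20 genes. Gene positions were shuffled 1000 times. The clock lists were added after the data were seen and set against 10000 random lists matched on expression.

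The methods were tested on simulated counts for this comparison. Among 50078 simulated genes, edgeR recovered 0 of 100 genes changed by 1 on the log2 scale and 37 of 100 changed by 2, and it called 4 unchanged genes. On 51047 simulated genes DESeq2 recovered 20 and 84 and called 127 unchanged genes. Its calls there thus held more unchanged than changed genes, above the nominal error rate. Few genes were changed in the simulation, so that share does not carry over to calls on the real counts. Camera recovered 2 of 2 shifted lists and called 0 unshifted lists. The simulated genes varied independently, so this does not test camera on lists whose genes vary together.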

Results

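The series measured transcripts in young flower buds of Brassica napus from 3 WT and 3 mutant samples of an F2 population scored for the double flower. Total counts were 13876719, 14010378 and 14699030 in the WT libraries and 13900416, 14929935 and 15140165 in the mutant libraries. After filtering, 51047 genes were tested. The single comparison, mutant against WT, asks which genes differ between buds of plants with the opposite flower forms.

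All 5 tested copies of AP2, the floral homeotic gene that specifies sepals and petals and restrains AGAMOUS, were lower in every mutant library than in any WT library. Their sum was 115 ± 17.5 CPM in WT and 57.6 ± 6.46 CPM in the mutant (SD, n = 3 each), 1.99-fold lower. Copies of SHP1, a carpel and ovule MADS-box gene, summed to 9.96 ± 1.66 CPM in WT and 38.3 ± 20.2 CPM in the mutant. No copy of AP2 or SHP1 passed edgeR's test over all genes. Groups were likewise apart in 35.6% of all tested genes, so the separation of AP2 is not particular to it. Camera with a preset correlation put cell division genes lower in the mutant and wounding, defence and ethylene genes higher, calls that were lost for each list (adjusted p = 0.75 with an estimated correlation). Mutant replicate 1 carried part of the cell division shift, at -2.35 against 0.02 and -0.07 in the other mutant libraries. The WT libraries were at 0.40, 1.13 and 0.79. Without mutant replicate 1 the list median went from -1.19 to -0.78. Morning genes of the circadian clock were several-fold higher in all 3 mutant libraries, with LHY copies at 41.9 ± 8.26 CPM in WT and 282 ± 104 CPM in the mutant.

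With edgeR's quasi-likelihood test no gene passed an adjusted p of 0.05, and the smallest adjusted p was 0.0834. At an unadjusted p under 0.05 the same test listed 13122 genes, 7471 higher and 5651 lower. DESeq2 called 5839 genes, 3697 higher and 2142 lower, and limma-voom called 0. Without mutant replicate 1, which lay apart from the other libraries, edgeR called 19 genes, 12 higher and 7 lower. The groups did not overlap in 18167 of the 51047 genes, 35.6%, where chance gives 10% on average over splits. Genes vary together, so this share is not a test. Of the 5576 tested genes that DESeq2 called, 5420 had groups that did not overlap. DESeq2 selected them on the same counts, so this is no separate support. In simulated counts edgeR recovered 0 of 100 genes with a log2 change of 1. Few genes were changed in that simulation, so it sets no limit on what the test could call here.

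In the floral organ identity list, 6 of 60 tested genes passed edgeR's test adjusted over the list alone, 1 higher and 5 lower, and 0 passed over all genes. Without WT replicate 1 none passed over the list (0 calls), 2 passed without WT replicate 2, and 3 passed without WT replicate 3, mutant replicate 1 or mutant replicate 3. Without mutant replicate 1 these were SEP4 and the AP2 copies BnaCnng39690D and BnaC01g01710D. AP2 copies fell on C01 (BnaC01g01710D, starting at 872199; 27.2 ± 7.76 to 9.62 ± 1.81 CPM; 2.82-fold; adjusted p = 0.0133 over the list alone, edgeR). The unplaced C copy BnaCnng39690D fell from 31.3 ± 4.42 to 15.4 ± 1.78 CPM, 2.03-fold, and BnaA01g34730D on the unplaced part of A01 fell from 13.1 ± 1.72 to 5.96 ± 1.38 CPM. BnaCnng71740D also fell, and BnaA03g53830D, at 31.4 ± 2.59 and 21.6 ± 3.33 CPM, did not pass. SEP4 (BnaC07g22490D, C07 from 28923638 to 28925702), a SEPALLATA gene of floral meristem and organ identity, fell from 7.02 ± 1.91 to 1.67 ± 0.42 CPM (log2 fold change -2.07 ± 0.34 SE). A copy of SHP1 (BnaA04g01810D) was the gene that rose. Without mutant replicate 2, 2 genes passed as higher and 4 as lower. With any other single library left out, 0 passed as higher, so the SHP1 call was lost. The list median was -0.09 on the log2 scale and camera did not call it (adjusted p = 0.559).

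The B-class genes were close between groups relative to their spread. AP3, 4 copies, summed to 302 ± 35.7 CPM in WT and 261 ± 77.0 CPM in the mutant (exact permutation p = 0.7), and PI, 7 copies, to 391 ± 58.7 and 352 ± 111 CPM (exact permutation p = 0.6). The C-class gene AG had 1 tested Arabidopsis-named copy at 33.0 ± 8.66 and 23.6 ± 10.6 CPM, and with 3 Brassica-named copies the sum was 86.4 ± 21.1 and 61.4 ± 19.2 CPM (exact permutation p = 0.3). SEP3, 6 copies, stood at 109 ± 38.4 and 108 ± 12.7 CPM. AP1, 3 Arabidopsis-named copies, stood at 109 ± 11.3 and 84.1 ± 10.1 CPM with no overlap between groups. Brassica-named AP1 copies such as BnaA07g24360D are not in this sum. Of 210 symbols with a tested copy, 38 were higher and 60 lower in every mutant library. Each of these has an exact permutation p of 0.1, the smallest that 3 against 3 allows, and no symbol passes after adjustment (smallest adjusted p = 0.214).

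**Figure D1:**
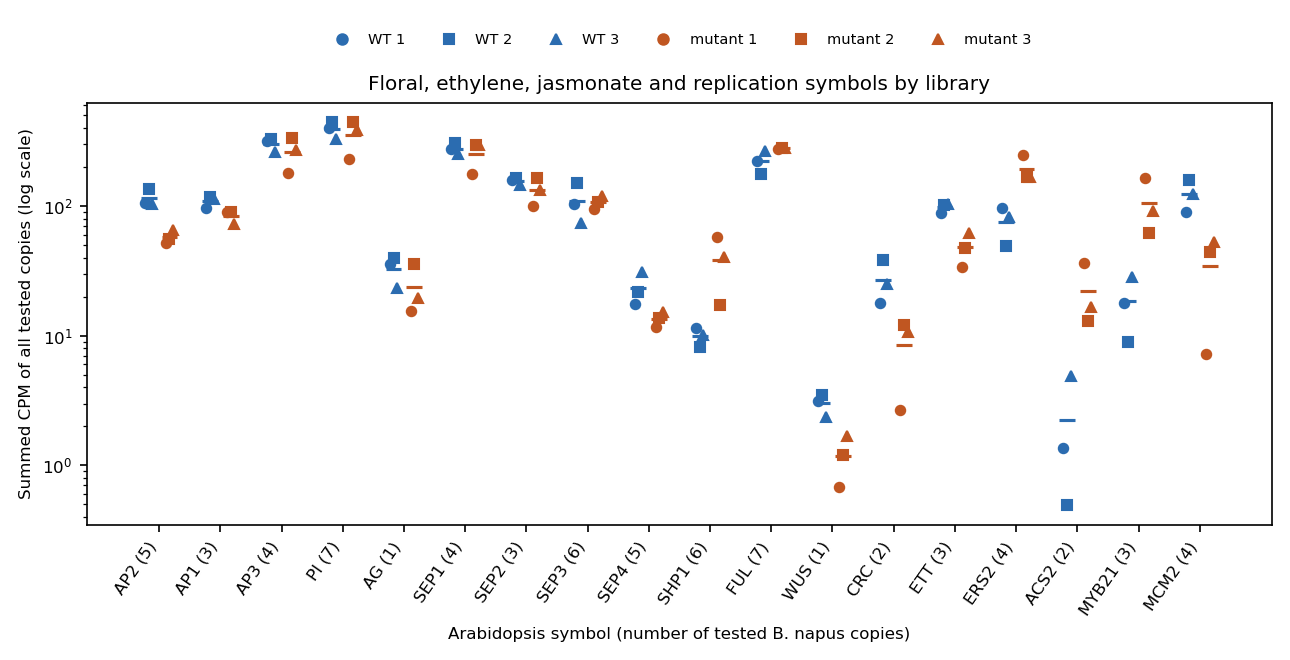
Summed CPM of all tested copies of 18 symbols in each library on a log axis, with WT in blue, mutant in orange and short lines at the group means. AP2 sums lie between 104 and 135 CPM in WT and between 52.3 and 64.8 CPM in the mutant.

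Among regulators of AGAMOUS and floral boundaries no gene of 69 passed over the list alone (0 calls, camera adjusted p = 0.912), and DESeq2 called 1 higher and 4 lower. Without mutant replicate 3, 2 passed as lower. The most abundant members were HUA1 (BnaA05g26510D, 124 ± 14.6 and 172 ± 19.5 CPM) and SEU (BnaA02g33130D, 132 ± 28.1 and 139 ± 23.1 CPM). ETT, an auxin response factor of the gynoecium, was lower in every mutant library in all 3 copies (sum 97.8 ± 7.87 and 47.9 ± 14 CPM), as were both copies of CRC, a carpel gene (26.9 ± 10.3 and 8.50 ± 5.11 CPM). The shoot and floral meristem list had 0 of 40 genes called over the list alone (3 lower without mutant replicate 1, and 1 higher and 3 lower without mutant replicate 2) and a median of -0.45. Camera with a preset correlation called it lower (adjusted p = 0.026), and the call was lost (adjusted p = 0.75 with an estimated correlation), as it was without WT replicate 3 (adjusted p = 0.168). ERECTA, a receptor kinase of stem and organ growth, stood at 153 ± 20.2 and 67.7 ± 31.7 CPM for BnaC08g32980D and at 108 ± 17.4 and 50.2 ± 18.9 CPM for BnaA09g40540D. The stem cell gene WUS had 1 tested copy (BnaA09g09400D, 3.0 ± 0.59 and 1.19 ± 0.50 CPM; edgeR adjusted p = 0.137), and 0 of 3 copies of CLV3 passed the filter. In the carpel and ovule list, 0 of 29 genes passed over the list alone (5 higher and 1 lower without mutant replicate 2; camera adjusted p = 0.978), and its most abundant members were ANT copies BnaC07g46770D (42.8 ± 3.28 and 42.7 ± 10.1 CPM) and BnaCnng72090D (36.1 ± 5.87 and 34.4 ± 6.56 CPM).

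Flowering time genes split by symbol. Of 51 tested, 2 rose and 3 fell in edgeR's test adjusted over the list alone, and camera gave an adjusted p of 0.912. These calls were lost without WT replicate 2 or any of the 3 mutant replicates (0 calls in each case). Without WT replicate 1 only the SPL9 copy BnaA05g02680D passed (edgeR adjusted p = 0.048 over the list alone). Without WT replicate 3, 1 higher and 1 lower gene passed. The SOC1 copy BnaCnng36880D (0.0774) and the 3 SPL9 copies (0.102 each) did not pass there. The SOC1 copy BnaCnng36880D, a floral promoter, rose from 12.3 ± 2.40 to 29.7 ± 9.28 CPM. SPL9, a phase change regulator under miRNA control, fell in 3 copies, among them BnaA04g24340D (50.7 ± 6.11 to 30.7 ± 3.82 CPM) and BnaC04g02520D (32.3 ± 4.06 to 15 ± 4.75 CPM).

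In the anther, tapetum and pollen wall list 2 of 49 genes rose over the list alone, both TKPR1 copies (BnaAnng25870D, 16.7 ± 6.21 to 70.2 ± 15.9 CPM, and BnaC05g07060D, 14.3 ± 3.64 to 39.3 ± 12.3 CPM). The rest of this list differed between libraries of the same group. Its median, relative to the mean of each gene, was 0.65, 2.23 and -1.22 in WT and -3.09, -0.23 and 3.13 in the mutant. With group means removed its genes had a median pairwise correlation of 0.65 over the libraries, across genes, against an upper bound of 0.07 for random lists of matched expression. The median fold change was 0.49 and the mean 0.87 on the log2 scale, whereas camera put the list lower (adjusted p = 0.696). Without mutant replicate 3 the median was -3.08, and camera called the list lower (adjusted p = 0.00154; adjusted p = 0.687 with an estimated correlation). The TKPR1 calls were lost without WT replicate 1 or mutant replicate 2 (0 calls over the list). That of BnaC05g07060D was also lost without WT replicate 2 (edgeR adjusted p = 0.101 over the list alone). In the mature pollen list 8 of 34 genes were tested, and 3 VGD1 copies rose and both TUA1 copies fell over the list alone. Camera gave an adjusted p of 0.267, and without mutant replicate 2 it called the list higher (adjusted p = 0.00981; adjusted p = 0.813 with an estimated correlation). Without mutant replicate 1 the median went from 2.39 to 1.39 and 0 genes passed over the list, as was the case without WT replicate 1, WT replicate 2 or mutant replicate 3. Summed over 5 copies, VGD1 was at 4.31 CPM in mutant replicate 2 and 6.24 CPM in WT replicate 3, so its groups overlap. The VGD1 copy BnaA05g00810D rose from 0.74 ± 0.29 to 4.13 ± 3.01 CPM, and the tubulin copy BnaA06g37700D fell from 193 ± 67.4 to 81.5 ± 30.3 CPM.

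Starch and sucrose genes gave the most calls over a list alone, 9 higher and 15 lower of 75, with no shift of the whole list (camera adjusted p = 0.231). Calls over the list numbered 1 higher and 5 lower without WT replicate 2, the fewest of any left-out library, and 6 higher and 14 lower without mutant replicate 1. The genes that fell include copies of the glucan water dikinase GWD1 (BnaA09g47750D, 210 ± 26.0 to 60.2 ± 10.8 CPM, 3.48-fold; edgeR adjusted p = 0.0027 over the list alone), BnaA08g25580D (40.3 ± 1.88 to 20.6 ± 0.73 CPM) and the beta-amylase BAM3 (BnaC01g21190D, 16.9 ± 0.86 to 4.89 ± 1.00 CPM). Another GWD1 copy had a log2 fold change of 0.92, and the beta-amylase BAM1 rose in 2 copies (sum of 4 copies 202 ± 56.5 and 363 ± 51.3 CPM). BAM3 was lower in every mutant library in 4 of 4 copies, PHS2, DPE1 and DPE2 in 2 of 2 each and GWD1 in 3 of 5. The vacuolar invertase BFRUCT4 (BnaC08g41390D) rose from 27.0 ± 7.18 to 86.0 ± 14.1 CPM and lies in a block of C08 whose genes shifted together between libraries. None of 205 pectin-modifying genes passed over the list alone (0 calls, camera adjusted p = 0.417), and DESeq2 called 17 higher and 25 lower. Without mutant replicate 2, 22 passed as higher and 5 as lower. The most abundant were BnaC05g39340D at 55.8 ± 26.1 and 75.1 ± 29.1 CPM and BnaC01g37010D, inside the shifted C01 block, at 55.1 ± 29.8 and 65.8 ± 25.8 CPM.

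The ethylene list, 62 genes, had 2 higher and 1 lower gene over the list alone and was called higher by camera (median 0.33, adjusted p = 0.0034; adjusted p = 0.75 with an estimated correlation). Without mutant replicate 1 its median was 0.22 (camera adjusted p = 0.0211; adjusted p = 0.914 with an estimated correlation) and 0 genes passed over the list. Also 0 passed without WT replicate 2 or mutant replicate 3, against 6 higher and 2 lower without mutant replicate 2. ACS2, a synthase of the ethylene precursor (BnaA10g00470D), rose from 1.40 ± 1.01 to 13.5 ± 7.60 CPM, and the CTR1 copy BnaC04g41700D, named for a kinase that represses ethylene signalling but matched by many genes, fell from 11.7 ± 1.67 to 4.37 ± 0.73 CPM. All 4 copies of the receptor ERS2 were higher in every mutant library and were called by DESeq2 (sum 75.9 ± 24.4 and 194 ± 48.1 CPM). BnaA08g27820D was the ERS2 copy that rose over the list alone (35.0 ± 10.2 to 73.7 ± 6.75 CPM). In the jasmonate list, 5 of 42 genes rose and 8 fell over the list alone (camera adjusted p = 0.351). Camera called the list lower without WT replicate 2 (adjusted p = 0.049; adjusted p = 0.68 with an estimated correlation), and put it higher, uncalled, without symbols matched by over 12 genes such as LOX2 (adjusted p = 0.187). Calls over the list numbered 1 higher and 0 lower without WT replicate 1 or mutant replicate 3, and 5 higher and 0 lower without mutant replicate 2. The stamen and petal growth factor MYB21 rose in 3 copies (BnaC06g29460D, 4.88 ± 1.17 to 20.1 ± 4.35 CPM), and the biosynthetic lipoxygenase LOX2 fell in 7 (BnaAnng34320D, 56.1 ± 25.5 to 20.2 ± 2.61 CPM). Of 32 cytokinin genes the activating enzyme LOG1 rose in 1 copy (BnaA07g13770D, 1.71 ± 0.38 to 6.24 ± 1.93 CPM; camera adjusted p = 0.218), a call kept only without mutant replicate 2 when single libraries were left out. Of 39 auxin genes 0 passed (camera adjusted p = 0.359), with ARF6 (BnaC05g23210D) at 160 ± 16.6 and 145 ± 4.11 CPM and ARF8 (BnaC06g27170D) at 110 ± 13.9 and 92.1 ± 16.2 CPM. The gibberellin list, 0 of 17 genes called, was lower by camera (median -0.42, adjusted p = 0.0454; adjusted p = 0.75 with an estimated correlation), a call lost without WT replicate 1 (median -0.21, adjusted p = 0.181) and without mutant replicate 1 (adjusted p = 0.0511). Its DELLA genes RGA stood at 84.4 ± 5.08 and 63.1 ± 8.12 CPM (BnaA09g18700D) and at 61.3 ± 11.3 and 62.2 ± 4.61 CPM (BnaA06g34810D).

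The cell division list had the smallest p by camera at the preset correlation, with a median of -1.19 over 49 genes (adjusted p = 1.11e-07; adjusted p = 0.75 with an estimated correlation). Over the list alone 1 gene rose and 4 fell, 1 rose and 7 fell without mutant replicate 1, and 1 rose and 0 fell without WT replicate 3. None passed (0 calls) without WT replicate 1, WT replicate 2, mutant replicate 2 or mutant replicate 3. The replication licensing factor MCM2 (BnaA08g04370D) fell from 15.4 ± 3.96 to 2.64 ± 1.41 CPM, and its 4 copies summed to 124 ± 34.0 and 34.5 ± 24.1 CPM. Copies of the G1 cyclin CYCD3.1 fell (BnaA08g11350D, 6.33 ± 1.55 to 2.47 ± 0.72 CPM). The calls of BnaA08g11350D and of the CYCD3.1 copy BnaC03g77070D were lost with any single library left out. A CYCB1.2 copy in the shifted C09 block (BnaC09g12990D) rose from 18.1 ± 6.26 to 45.5 ± 6.13 CPM. Mutant replicate 1 was the lowest library for this list, at -2.35 against 0.02 and -0.07 in the other mutant libraries. The WT libraries were at 0.40, 1.13 and 0.79. Without mutant replicate 1 the list median was -0.78 (camera adjusted p = 6.86e-09; adjusted p = 0.647 with an estimated correlation).

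Photosynthesis genes had a median of -0.66 with 0 of 63 called over the list alone (camera adjusted p = 9.64e-05; adjusted p = 0.85 with an estimated correlation). Here too mutant replicate 1 lay far below, at -1.54 against 0.20 and 0.22 in the other mutant libraries. Without that library the median was -0.25 (camera adjusted p = 0.0443; adjusted p = 0.914 with an estimated correlation), with 3 genes higher and 0 lower over the list alone. The Rubisco small subunit copy BnaA04g08640D stood at 1095 ± 148 and 617 ± 360 CPM, and BnaC04g30870D at 807 ± 125 and 446 ± 268 CPM. Epidermis markers had a median of -0.34 and 0 of 28 called over the list alone (camera adjusted p = 0.00652; adjusted p = 0.75 with an estimated correlation), with the wax gene CER1 (BnaCnng09200D) at 899 ± 46.2 and 551 ± 245 CPM and CER6 (BnaA09g28510D) at 319 ± 27.0 and 206 ± 87.3 CPM. Mutant replicate 1 was at -0.51 for epidermis markers against 0.00 and -0.04 in the other mutant libraries. Without that library the median was -0.24 (camera adjusted p = 0.0213; adjusted p = 0.571 with an estimated correlation). Vascular markers were not shifted as a list (camera adjusted p = 0.912), and the xylem protease copy XCP1 (BnaC01g26050D) rose from 0.58 ± 0.06 to 11.8 ± 8.58 CPM over the list of 48, a call lost without WT replicate 1 or WT replicate 2. Of 6 tested XCP1 copies, 3 were higher and 2 lower in every mutant library. The secondary wall cellulose synthases CESA4, CESA7 and CESA8 were lower in every mutant library in both copies of each (sums 5.44 ± 0.55 and 1.60 ± 1.44, 9.07 ± 2.05 and 3.57 ± 1.65, and 5.6 ± 0.88 and 1.59 ± 1.52 CPM), and 0 of these copies were called by DESeq2. Only 2 root marker genes passed the filter, both SCR (BnaC08g25070D, 16.0 ± 1.31 and 15.7 ± 1.01 CPM, and BnaA09g34140D, 14.6 ± 2.42 and 11.7 ± 0.52 CPM), so the root list was not tested.

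Wounding and defence genes had a median of 1.73 over 40 genes (camera adjusted p = 0.00025; adjusted p = 0.75 with an estimated correlation), and 5 rose over the list alone with 0 lower. Without WT replicate 3, 20 passed as higher and 1 as lower, and without WT replicate 1, 2 passed as higher. Mutant replicate 1 was the highest library at 1.30, and without it the median was 0.96 (camera adjusted p = 0.0022; adjusted p = 0.695 with an estimated correlation). The glucanase PR2 rose in 3 copies, such as BnaA09g36610D (10.6 ± 3.25 to 39.6 ± 15.3 CPM), and PR5 in BnaA07g21910D (7.07 ± 1.28 to 22.6 ± 7.83 CPM). Heat, cold and drought genes had a median of 0.54 over 24 genes (camera adjusted p = 0.00652; adjusted p = 0.75 with an estimated correlation). The call was lost without mutant replicate 2 (median 0.40, adjusted p = 0.0859), and the median was 0.36 without WT replicate 2. Over the list alone 7 genes passed as higher without WT replicate 1, 4 without mutant replicate 1 and 2 without WT replicate 2, and 0 without WT replicate 3, mutant replicate 2 or mutant replicate 3. With all libraries the heat shock factor HSFA2 was the single call over that list (BnaC03g26940D, 1.37 ± 0.37 to 5.62 ± 1.2 CPM). In the petal growth and pigment list 3 of 36 genes rose and 9 fell over the list alone (median -0.50, camera adjusted p = 0.0454; adjusted p = 0.75 with an estimated correlation). The list call was lost without WT replicate 1 (adjusted p = 0.102), without WT replicate 3 (adjusted p = 0.116) and with scaling by library total (adjusted p = 0.0742). Mutant replicate 1 was at -0.76 against -0.01 and -0.01 in the other mutant libraries. The WT libraries were at 0.32, 0.22 and 0.31. Without mutant replicate 1 the median was -0.49 (camera adjusted p = 0.0443, and 0.571 with an estimated correlation). In that setting 2 genes rose and 11 fell over the list alone. Over the list alone 0 rose and 2 fell without WT replicate 2, the fewest of any left-out library. KLU, which prolongs organ growth, fell in BnaA06g08740D (66.1 ± 10.8 to 27.9 ± 3.43 CPM) and BnaC05g10050D (57.5 ± 17 to 24.5 ± 5.20 CPM). TCP4, which ends organ growth, fell in BnaA03g33680D (15.6 ± 2.41 to 6.21 ± 1.82 CPM).

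**Figure D2:**
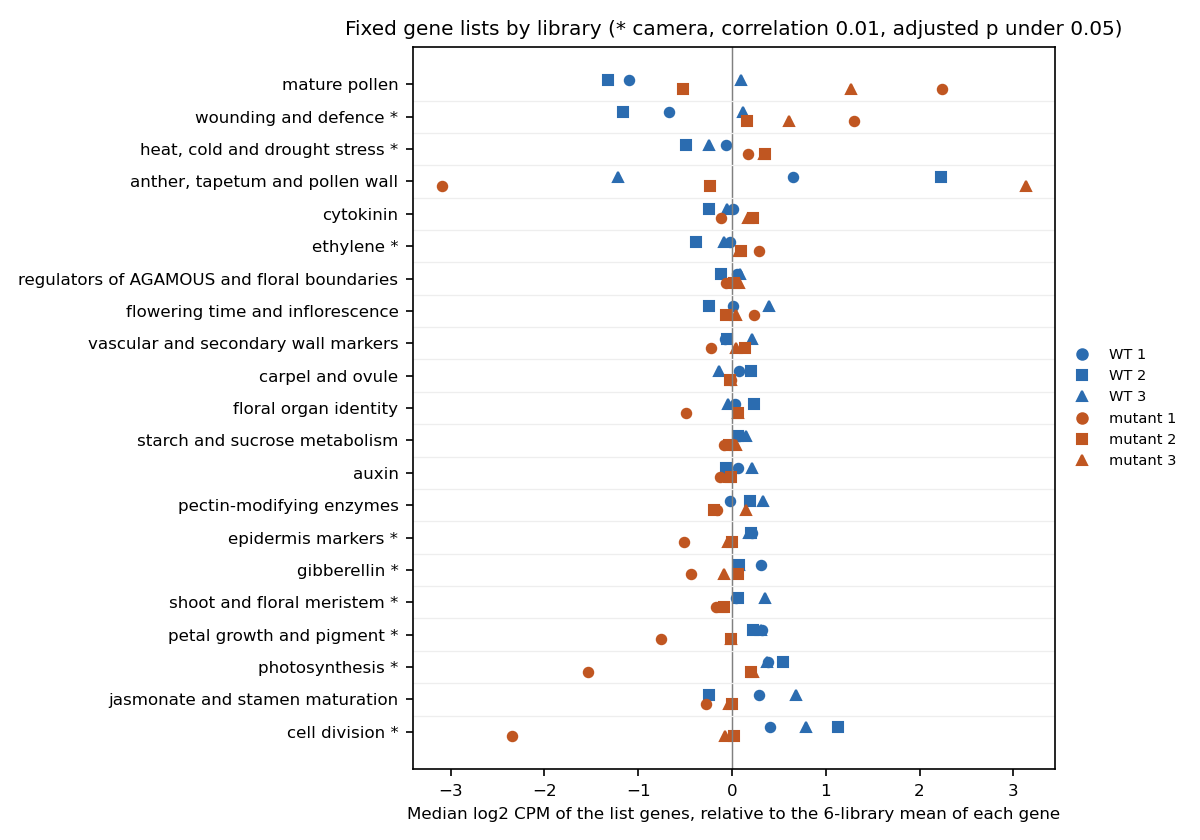
Median log2 CPM of each tested list in each library, relative to the 6-library mean of each gene, with WT in blue and mutant in orange. Mutant replicate 1 lies at -2.35 for cell division and -1.54 for photosynthesis, and the anther list spans from -3.09 to 3.13 within the mutant group.

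Camera's preset correlation of 0.01 is well below the estimated values for several lists, which reach 0.857 for photosynthesis, and with estimated correlations 0 of the 21 lists were called. With fry the smallest adjusted p was 0.232. Calls over the lists alone depended on single libraries, with 32 calls in 7 lists without WT replicate 2 and 100 in 12 lists without mutant replicate 2. Median, mean and camera direction also differ in sign for the lists on AGAMOUS regulators (median 0.01, mean -0.03, lower), flowering time (0.01, -0.08, lower), carpel (-0.07, 0.07, higher), pectin (-0.17, 0.07, lower) and vascular markers (0.01, 0.05, lower).

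The genes with the smallest adjusted p included clock and light-regulated genes. In edgeR's test 28 genes shared the smallest adjusted p of 0.0834, 16 higher and 12 lower, and they were read after their values were seen. LHY, a morning repressor of the clock, stood at 14 ± 2.95 and 112 ± 36.5 CPM in BnaA10g00780D and at 6.0 ± 1.03 and 86.4 ± 41.4 CPM in BnaC05g00840D. Both passed without mutant replicate 1 (edgeR adjusted p = 0.0278 and 0.0173), as did the CCA1 copy BnaA05g01050D (8.55 ± 3.18 and 65.9 ± 22.7 CPM; adjusted p = 0.0474). The evening gene ELF4 was lower (BnaC03g72320D, 37.5 ± 3.77 and 7.78 ± 0.39 CPM), as were the blue light receptor relative ADO2 (BnaC07g02620D, 26.1 ± 1.88 and 6.18 ± 1.48 CPM), CONSTANS-LIKE 9 (BnaA03g30130D, 18.1 ± 1.62 and 3.14 ± 0.80 CPM) and the glycine-rich RNA-binding gene GRP2A (BnaUnng05060D, 198 ± 12 and 48.1 ± 10.2 CPM). Outside the clock, the chitinase CHB4 (BnaA04g25220D) stood at 0.16 ± 0.08 and 17.9 ± 12.2 CPM, and alpha-aminoadipic semialdehyde synthase, a lysine catabolism enzyme (BnaA01g03680D), at 41.2 ± 7.81 and 169 ± 18.0 CPM. Thiamine thiazole synthase (BnaA02g27980D), called by edgeR without mutant replicate 1, stood at 414 ± 23.8 and 102 ± 35.8 CPM.

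Terms were described from the DESeq2 calls, since the main test gave 0 calls and so 0 terms. In simulated counts DESeq2 called 127 unchanged genes, more than the changed genes it recovered. Few genes were changed in that simulation, so this share does not carry over to the calls here. Terms and chromosomes rest on calls whose error rate is uncertain. Among the higher genes, protein serine/threonine kinases held 246 calls where 129.5 fell by proportion (Fisher's exact test, adjusted p = 3.51e-20), and chitinases held 16 of 42 (adjusted p = 8.31e-07). With mutant replicate 1 left out, kinases held 92 calls where 66.3 fell by proportion (adjusted p = 0.0285) and chitinases 3 of 37 (adjusted p = 1), so the chitinase term rests on that library. Defense response genes held 42 calls against 21.5 by proportion, and 27 against 9.9 without that library. Xyloglucan transferases held 13 of 49, and 7 of 38 without it. Among the lower genes, DNA replication initiation held 14 of 24 (adjusted p = 3.28e-11), the MCM complex 13 of 20 and microtubule genes 20 of 64. Pectate lyases (K01728) held 15 of 57 (adjusted p = 4.56e-06), lipoxygenases (K00454) 8 of 25 and AP2-type factors (K09284) 6 of 14 (adjusted p = 0.000976), and these 6 terms for lower genes passed without mutant replicate 1 too. D3 cyclins (K14505) held 6 of 16, and 2 of 15 without it (adjusted p = 1). Genes within a term are not independent, and with mutant replicate 1 left out 30 of the 83 terms for higher genes and 50 of the 63 for lower genes still passed.

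DESeq2 calls were spread evenly over the subgenomes, at 10.7% of A and 10.7% of C genes (Fisher's exact test, p = 0.879), but not over chromosomes. C01 had 15.5% called (adjusted p = 6.02e-12), A01 14.6% (adjusted p = 9.51e-08), A02 13% (adjusted p = 0.00302) and C02 12.7% (adjusted p = 0.0172). A03, at 8.4%, A07 and C08 were below the rest. Neighbouring genes are not independent, and edgeR's 0 calls gave no chromosome.

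Neighbouring genes shifted together in blocks that differed between libraries. Of 326 windows of 2 Mb, 33 had a range of over 0.6 between library medians on the log2 scale, whereas at most 3 did in 1000 shuffles of gene positions. On C02 from 4 to 8 Mb, 153 genes had medians of 0.50, 0.26 and 0.42 in WT and -0.58, -0.27 and -0.45 in the mutant libraries, and 53 of 56 DESeq2 calls there were lower. On C01 from 24 to 38 Mb medians were -0.32, -0.30 and -0.08 in WT and 0.16, 0.05 and 0.53 in the mutant, and 108 of 109 calls were higher. The A01 block from 12 to 20 Mb moved opposite to C01 but its groups overlapped, at 0.47, 0.54 and 0.00 in WT and 0.17, -0.24 and -0.91 in the mutant. On C09 from 8 to 22 Mb, 71 of 73 calls were higher. Blocks held 425 of the 5576 DESeq2 calls, 14.4% of their genes against 10.7% elsewhere.

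All windows, inside and outside these blocks, were also ranked by the gap between the groups. The groups did not overlap in 77 of the 326 windows, 23.6%, where chance gives 10% on average over splits. Among single genes the share was 35.6%. Windows vary together as genes do, so the share of windows is not a test. The widest gaps were 0.50 and 0.49 in the windows on C02 from 4 to 8 Mb, followed by 0.28 on C08 from 6 to 8 Mb (20 genes) and 0.28 on A02 from 2 to 4 Mb (190 genes). The A02 window had a range of 0.31, under the threshold of 0.6, with medians of -0.16, -0.14 and -0.16 in WT and 0.15, 0.14 and 0.15 in the mutant, and 38 DESeq2 calls higher and 3 lower.

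**Figure D3:**
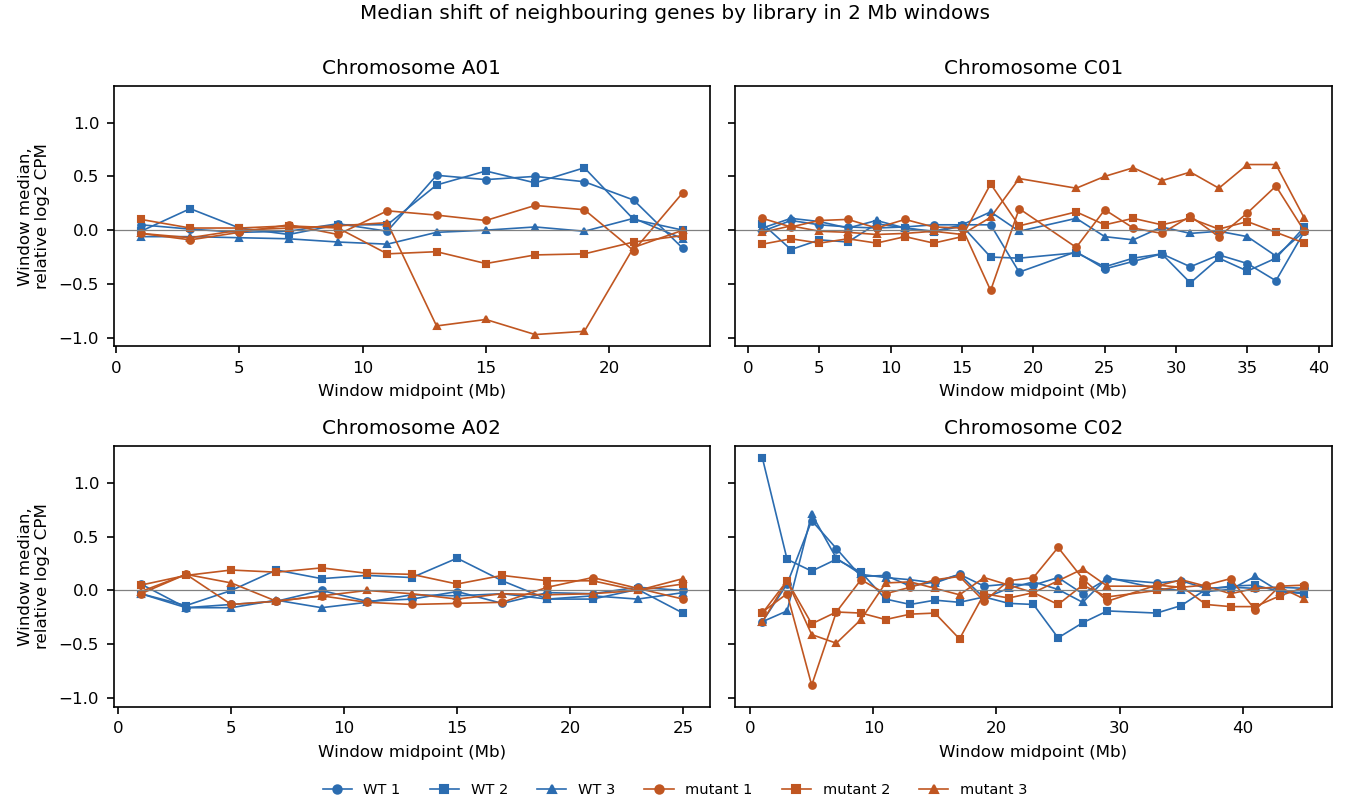
Median relative log2 CPM of the genes in each 2 Mb window along chromosomes A01, C01, A02 and C02, with 1 line per library, WT in blue and mutant in orange. Mutant replicate 3 lies near -0.91 over A01 from 12 to 20 Mb and near 0.53 over C01 from 24 to 38 Mb, and the groups separate over C02 from 4 to 8 Mb.

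The first principal component held 61.6% of the variance and set mutant replicate 1 against WT replicate 2. Correlations of log2 CPM were 0.890 to 0.934 within WT, 0.866 to 0.941 within the mutant and 0.656 to 0.921 between groups. With 3 libraries per group and a biological coefficient of variation of 0.36, the comparison has little power for small changes, and harvest time and phenotype scores per plant were not given in the sources used here.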

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

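The 5 gene-level fits beside the planned 15, the threshold of 0.10, the lists without symbols matched by over 12 genes, and terms and chromosomes from fits other than edgeR were chosen after the data were seen. The count of changed genes, 0 in the reported fit, was 5839 with DESeq2, 1 with limma on log2(FPKM + 1) and 1 on log2(FPKM + 0.1). Leaving out each replicate in turn gave 0 to 19 genes, and the 19 came without mutant replicate 1. With that library left out, edgeR with its legacy setting off gave 88 genes and DESeq2 3625. Weighting libraries by quality in limma-voom (weight 0.35 for mutant replicate 1) gave 359, and a threshold of 0.10 gave 1128. Other scalings, filters, limma-voom, robust edgeR and edgeR with the legacy setting off on all libraries gave 0. The replicate block also gave 0 genes, with a smallest adjusted p of 0.125. Same-numbered samples correlated at 0.09, 0.27 and -0.24 in their deviations, and 0 samples matched best with their own number, so numbers were not read as pairs.

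Camera called 9 lists, 7 to 10 when a replicate was left out, 9 with the replicate block, 8 by library total only, and 0 with an estimated correlation. Without symbols matched by over 12 genes it called 6 and lost the meristem (adjusted p = 0.103), gibberellin (0.11) and petal (0.0584) lists. All 9 kept the sign of their median in every setting. The anther list reversed without mutant replicate 3, and over the left-out replicates its median ran from -3.08 to 1.57. With the replicate block it was -1.69. Terms, 0 in the reported fit, numbered 146 with DESeq2, 135 with DESeq2 at 2-fold, 108 with DESeq2 and 8 with edgeR (legacy off) without mutant replicate 1, 16 with quality weights and 0 to 6 when a replicate was left out. Chromosomes, also 0, numbered 7 with DESeq2 at any fold and at 2-fold, 9 with DESeq2 without mutant replicate 1, and 1 with quality weights and with legacy off without that library. The cause of the difference between DESeq2 and edgeR was not tested. Of 127 named genes, 108 kept their direction in all 20 other fits, among them all 77 that were called within a list or were chosen for small p-values. Those 77 were picked from these same libraries, so their kept direction is no separate support. A count of 0 allows up to 3 counts, 0.198 to 0.216 CPM in these libraries.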

Other observations

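The tests on mutant replicate 1 and on chromosome blocks, the clock index and the count of splits for edgeR were chosen after the result was seen, whereas the harvest time test and the counts of splits for DESeq2 and camera were written before theirs.

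Copies of another AP2-type factor, TOE3, were also lower. DESeq2 called TOE3, a relative of AP2, lower in BnaA07g12050D (10.8 ± 4.48 and 3.44 ± 0.29 CPM, adjusted p = 0.00301) and in BnaC07g16190D (21.1 ± 6.52 and 8.43 ± 2.93 CPM, adjusted p = 0.00887). Both were lower in 3 of 3 mutant libraries than in any WT library, where groups were apart in 35.6% of all tested genes. Of the 14 tested AP2-type orthologs, 6 were called lower by DESeq2, and they were 4 AP2 and both TOE3 copies. The rest of the 14 were not called lower.

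Clock genes differed between the groups in every library. All 19 morning-phase genes (LHY, CCA1 and PRR9 copies) had fold changes above 0, with a median of 2.06 on the log2 scale against bounds of -0.32 and 0.37 for the central 95% of random lists, and DESeq2 called 15 of them higher, also 15 without mutant replicate 1. The mean log2 CPM of morning minus evening genes was -1.63, -1.85 and -1.65 in WT and 0.40, 1.16 and 1.07 in the mutant, a difference of 2.59. A state peculiar to mutant replicate 1 is argued against, since its index of 0.40 is the lowest of its group. A harvest of the groups at different times of day may explain the pattern: evening genes other than ELF4 and LKP2 had a median of -0.32, and starch breakdown genes outside the fixed list lay at percentile 0.01 of random lists with a median of -0.55. Of these 24 starch genes 21 had fold changes below 0, and DESeq2 called 2 lower and 0 higher. Random lists drew genes separately, whereas list members may vary together, so percentiles and bounds can overstate a shift. A genotype that changes the clock cannot be told apart from a different harvest time, because harvest time is not given per plant. Starch genes such as GWD1 in the report may follow either.

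Mutant replicate 1 stood apart from the other 5 libraries. Leaf tissue in that sample is argued against, since its photosynthesis genes deviated by -1.85 in the median, below the bound of -0.16 for random lists. Length-dependent RNA loss is argued against by a Spearman correlation with coding length of 0.016 across genes, where other libraries reached 0.075 in size. An exchange of labels with a WT library is argued against: on genes that DESeq2 called without the placed library, it lay at a median position of 1.25 between the group means (0 for WT, 1 for mutant) and the highest WT library at 0.41, while a single wrong label from outside remains open. A defence or senescence state of that sample cannot be told apart from other causes, because its wounding and defence genes, at 1.56, and its cell division genes, at -2.83, were seen shifted before they were tested.

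The blocks of neighbouring genes are not chance neighbours, with 33 windows past the range threshold and at most 3 in shuffles. Exchange or unequal dosage of homeologous segments, which can segregate in an F2 of this allotetraploid, is a candidate explanation for A01: of the 10 windows on other chromosomes that ran most opposite to its block, 8 lay on C01, where 2 is the upper bound by chance (exact hypergeometric test over windows, p = 1.49e-09; neighbouring windows are not independent). The count was 4 of 10 on A01 for C01 from 24 to 38 Mb and 5 of 10 on A02 for C02 from 16 to 18 Mb, but 1 on A02 for C02 from 4 to 8 Mb and 0 on A09 for C09 from 8 to 22 Mb. Every remaining block had a count of at most 2. Only the chromosome of the same number was counted, so a low count does not exclude a partner segment elsewhere. Genotype as labelled cannot set every block, because groups were apart in 3 of 8 blocks of several windows. Reads of a divergent parental copy placed on the other homeolog cannot be told apart from dosage without sequence, including in the A02 window from 2 to 4 Mb, which lies outside the blocks, with its gap of 0.28 between the groups, and linkage of C02 or A02 to the flower form was not tested.

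Whether chance can be excluded is limited by the design, since 6 libraries make 10 splits and no share under 0.05 is possible. The real split gave 0 genes with edgeR and the highest other 0, so the count of 10 splits as large says nothing. At an unadjusted p under 0.05 edgeR listed 13122 genes for the real split and at most 2740 for another. With DESeq2 the real split gave 5839 genes and the highest other 370, so 1 split was as large. With camera the real split gave 9 lists and the highest other 11, so 3 splits were as large.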
